A study of Mus musculus with 8 samples.

How the data were processed

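Total RNA of whole lungs from 3 control and 5 ventilated NOD/shi mice was extracted with Trizol, cleaned with an RNeasy kit with DNase treatment and checked on a Bioanalyser, per the labels. It was amplified to biotin-labelled cRNA with a MessageAmp kit (Ambion) and hybridised to Illumina bead arrays, per the labels. The scanner, its software and the ventilation protocol are not given in the sources used here.

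The authors deposited probe intensities that are not normalized, per the file headers; the values are linear, and all lie above 0, so that background had not been subtracted. For each intensity the deposited file gives a detection p-value, per the file headers, which takes 798 steps on each array. The authors also deposited a value table whose intensities, set against those of the first file, equal them times 1 factor per array, so that all arrays have the same mean; 1 probe value was off its array's factor. That table is linear, not centred and not background-subtracted, and its medians were 31.7, 116 and 34.3 for controls 1 to 3 and 70.2, 42.5, 61.5, 82.5 and 30.9 for ventilated arrays 1 to 5.

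Of 25697 probes, 23978 carried 1 gene symbol in the platform annotation, 0 carried several and 1719 were not listed there and stayed unnamed. Symbols were checked against a RefSeq gene table, which held 23962 of the named probes and changed 0 symbols. The files name no genome build, so no coordinates are given.

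The intensities were processed in R 4.3.3 with limma 3.58.1. The function neqc corrected the background with negative controls inferred from the detection p-values, added an offset of 16, applied quantile normalization and took log2. The 13374 probes detected at p under 0.05 on at least 3 of the 8 arrays were kept. For each gene the probe with the highest mean was used, which left 10200 features, 9425 named and 775 unnamed; 2357 genes had more than 1 kept probe.

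Ventilated and control arrays were compared with lmFit and eBayes in limma, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05; log2 fold changes are ventilated minus control. Gene lists of pathways and cell types were tested with limma's camera at a preset correlation of 0.01 when at least 3 members were measured, adjusted over the 42 lists tested. The score of a list in a mouse is the mean over its genes of the log2 level minus the control mean, tested with an exact two-sided permutation test over all 56 splits. The lists, the tests and the rule for naming genes were fixed before the data were examined.

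The rule names the 10 genes with the largest rises and the 10 with the largest falls among those past the threshold whose groups did not overlap. It also names the largest 2 changes past the threshold on each list, or the member with the smallest p where none passed, and each sex-linked gene measured. It gave 64 genes, of which 38 passed. A gene detected on no array of a group has only a bound. Its fold is the mean of the other group against the mean, per array, of the lowest normalized signal among detected probes or the probe's own signal if higher, and is written as at least that fold.

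The fit was tested on simulated data with the sizes of the comparison of ventilated and control arrays, in 20 simulations of 10200 genes with 50 changed genes per fold. It recovered 1.5% of genes changed 1.5-fold, 22.6% at 2-fold, 79.9% at 4-fold and 93.8% at 8-fold, and 4.67% of its calls were unchanged genes. A list of 15 genes shifted by 1 was found in 20 of 20 simulations, and 0.05 of 41 unshifted lists per simulation. The simulated noise was independent between genes.

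Alternatives covered the background correction, normalization, deposited values, detection filter, choice of probe, variance model, array weights, thresholds, set test, replicate number as a block and each array left out. Alternatives for array brightness were added after the arrays were seen to differ: brightness as a covariate, the brighter 4 arrays (controls 1 and 3, ventilated 2 and 5) against the dimmer 4 as a block, each set alone, and the dimmest array of each group left out. Figures were drawn in Python 3.11.15 with matplotlib 3.10.9. Unnamed probes were tested and counted but not described, and the lists of mast cells and of sex-linked genes, with 1 and 2 measured members, were not tested.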

Results

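Messenger RNA levels were measured in whole lungs of 8 NOD/shi mice, a substrain of the non-obese diabetic inbred mouse, aged 6 to 12 weeks. Lungs of 3 mice that were not ventilated served as controls, and 5 mice had been mechanically ventilated. The series is labelled as a study of ventilator-induced lung injury, the damage that mechanical ventilation itself does to the lung. The comparison asked which lung transcripts differ between ventilated and non-ventilated mice. Ventilator settings, the length of ventilation, anaesthesia and the handling of the controls were not given in the sources used here. The labels number each lung as a sample of its own. The p-values of single genes and of list scores measure the spread between these samples. The p-values that camera gave for lists at the preset correlation rest instead on the spread between genes. They do not measure how far a list varies between mice. Each lung was hybridised to 1 single-colour bead array, on which 25697 probes were read.

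The arrays differed in brightness within both groups. Mean probe intensity was 332, 54.3 and 253 on control arrays 1 to 3, and 107, 212, 126, 87.4 and 321 on ventilated arrays 1 to 5. Probes detected above background numbered 14313, 8080 and 13299 on the controls and between 9765 and 13924 on the ventilated arrays. Control 2 was the dimmest array, and its Pearson correlation with the other arrays, across genes, was 0.846 to 0.899, whereas the lowest correlation between any other pair was 0.912. Genes are not independent replicates in these correlations. Control 1 carried more skeletal muscle RNA than the other lungs. Its skeletal muscle score was 2.26 above the mean of the controls on the log2 scale, against −1.45 in control 2, −0.81 in control 3 and at most −0.25 in the ventilated lungs. Its cardiac muscle score was 1.26, with ventilated 4 at 1.17. With 3 and 5 arrays, their number limits the precision of every value.

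**Figure D1:**
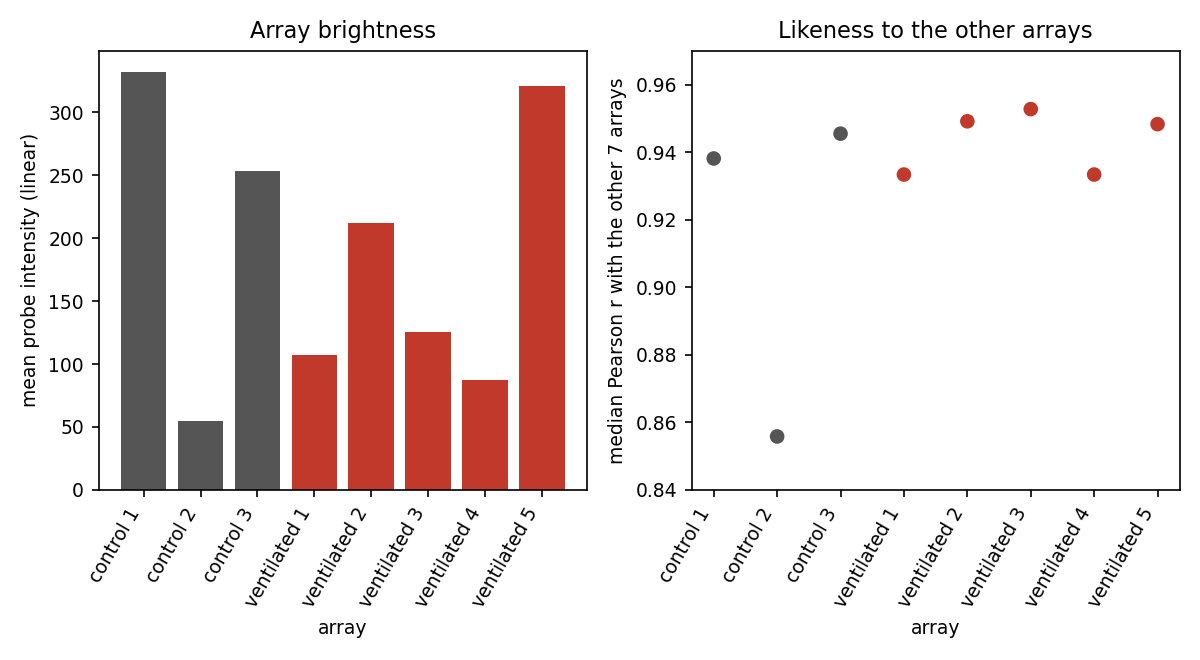
The bars show the mean probe intensity of each array on a linear scale, and the points show each array's median Pearson correlation with the other 7 arrays across 10200 features, with the 3 control arrays in grey and the 5 ventilated arrays in red. Control 2 has the lowest mean intensity, 54.3, and the lowest median correlation, 0.856.

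Ventilated lungs carried more transcript of the neutrophil genes Retnlg, S100a9 and S100a8, of Cdkn1a and of the metallothioneins Mt1 and Mt2, and less of the inducible heat shock gene Hspa1a. Retnlg (probe ILMN_2656504), a resistin-like gene transcribed in neutrophils, rose 36.2-fold, and S100a9 and S100a8, the subunits of calprotectin, rose 23.9-fold and 18.9-fold. Cdkn1a, which encodes the cell cycle inhibitor p21, rose 8.60-fold, and Hspa1a fell 12.4-fold, to a level detected on 2 of the 5 ventilated arrays and not detected on the others. Without control 2, on which S100a9 was not detected, the log2 fold change of S100a9 was 3.90, against 4.58 with all arrays. That of Hspa1a was −3.63 with all arrays, −4.67 without control 1 and −2.96 without control 2. In all, 204 of 10200 features differed at an adjusted p under 0.05, 129 of them higher and 75 lower in ventilated lungs, and 186 of the 204 carried a gene symbol. Of the 204, 196 changed at least 2-fold, 124 upward and 72 downward. An unadjusted p under 0.05 was reached by 1656 features, where 510 are expected on average if no feature differs. Array effects can also raise this number: control 2, ventilated 1 and ventilated 4 set against the other arrays gave 2278. All 204 had their 5 ventilated values on a single side of the 3 control values; this held for 13.2% of all features, against 3.57% by chance. The count fell to 68 without control 3 or without ventilated 3, to 91 without control 1, to 104, 73, 102 and 82 without ventilated 1, 2, 4 and 5, and to 164 without control 2. Of these 164, 125 were among the 204. With array brightness as a block 315 features were called, 202 of them among the 204. Within the 4 brighter arrays 11 were called, each of them also among the 204. The 4 dimmer arrays hold a single control.

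The largest rises were those of the neutrophil genes Retnlg, S100a9 and S100a8. Their log2 fold changes were 5.18 ± 0.40 (SE; adjusted p = 0.000348), 4.58 ± 0.46 (adjusted p = 0.00155) and 4.24 ± 0.33 (adjusted p = 0.000348). The normalized log2 level of S100a8 was 7.90 ± 0.33 (SD, n = 3) in controls and 12.14 ± 0.58 (SD, n = 5) after ventilation. Camp, which encodes the antimicrobial peptide cathelicidin, was not detected on any control array and was at least 4.01-fold higher in ventilated lungs (adjusted p = 0.0277). Il1r2, the decoy receptor for interleukin-1, was likewise undetected on the controls and at least 7.14-fold higher (adjusted p = 0.00077). Fpr2, a receptor for formylated peptides, rose by 2.78 ± 0.56 (adjusted p = 0.0347), a call lost in 7 of the 8 fits that left out 1 array. The other large rises were those of Pmvk, an enzyme of the mevalonate pathway (3.35 ± 0.39), Cdkn1a (3.10 ± 0.24), Mt2, a metallothionein (2.75 ± 0.35), and Mfsd2a, a transporter of lysophospholipids (2.70 ± 0.36). Without control 2 the log2 fold changes were 3.90 for S100a9, 2.10 for Fpr2 (adjusted p = 0.0502) and 2.75 for Pmvk. Retnlg, S100a9, Pmvk, Fpr2, Mt2 and Mfsd2a were detected on 2 of the 3 control arrays and on all 5 ventilated arrays. The size of the rises depended on the processing. Over the alternatives other than leaving out 1 array, the log2 fold change was 3.63 to 5.95 for Retnlg, 3.45 to 6.09 for S100a9 and 1.66 to 3.49 for Il1r2.

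**Figure D2:**
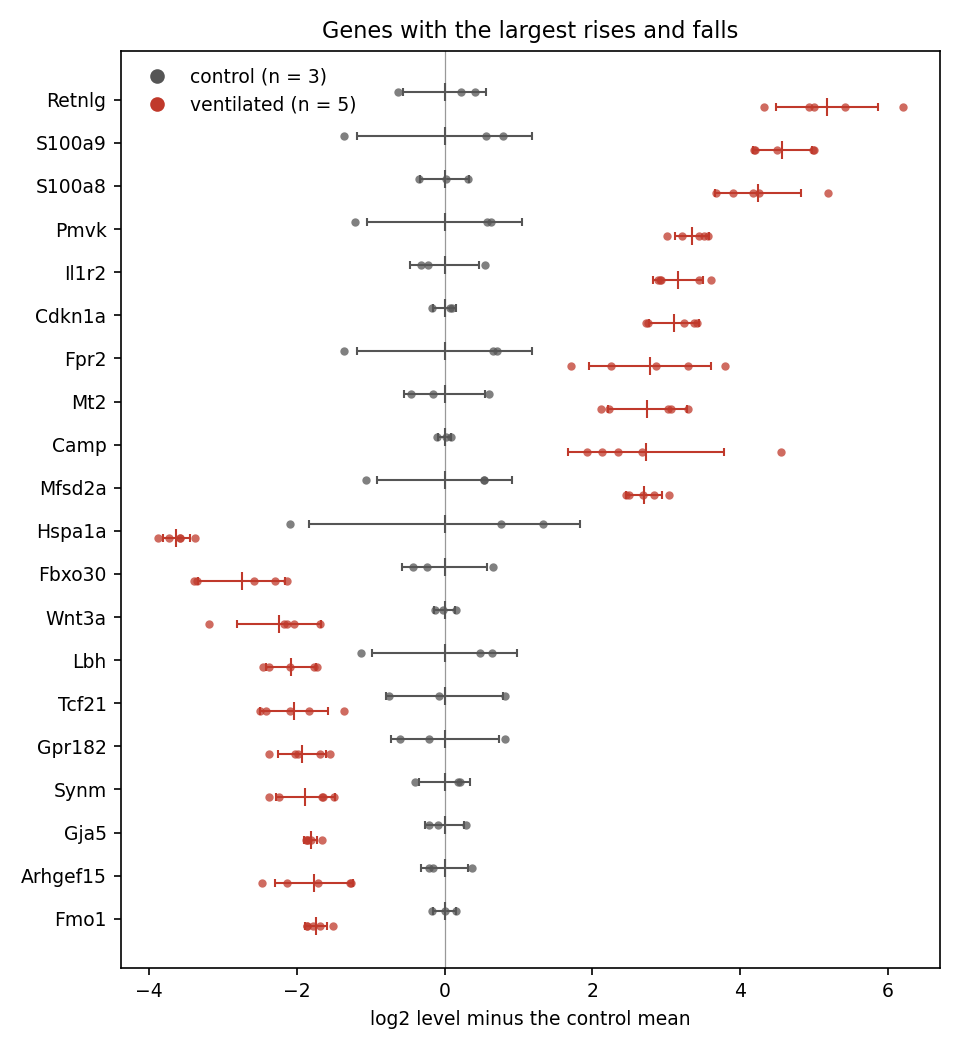
Each row shows a gene's normalized log2 level minus its mean over the controls, with a point per mouse, a tick at the group mean and a bar of 1 SD either side, for 3 control mice in grey and 5 ventilated mice in red and for the 10 named genes with the largest rises and the 10 with the largest falls. All ventilated values lie beyond all control values for every gene shown.

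The neutrophil list shifted upward. Of its 16 measured members 7 rose and none fell, or 13 and none when adjusted over the list alone, with a mean log2 fold change of 2.10 (adjusted p = 2.12e-16; adjusted p = 0.0952 with an estimated correlation). The score per mouse was 2.10 ± 0.47 (SD, n = 5) after ventilation, against a control SD of 0.05 (n = 3). In an exact two-sided permutation test p was 0.0179, the smallest that 56 splits can give. The list mean was 1.87 within the brighter arrays and 2.26 within the dimmer ones. The platelet list shifted upward by a mean of 0.56 (adjusted p = 0.0338; adjusted p = 0.211 with an estimated correlation), with none of 8 members past the threshold alone, and the erythroid list had a mean of 0.53 without passing (adjusted p = 0.0577). The erythroid mean was 0.28 without control 2, 0.74 without control 3, where it passed (adjusted p = 0.037), 0.18 within the brighter and 1.09 within the dimmer arrays. The platelet call was lost without control 3, ventilated 1 or ventilated 4, at means of 0.52, 0.50 and 0.54. Array brightness as a block also ended it, at a mean of 0.54 (camera adjusted p = 0.105). So did a common median, the deposited values, detection on all arrays and the brighter arrays alone, the last at a mean of 0.31. Over the alternatives other than leaving out 1 array the platelet mean was 0.16 to 0.83. Monocyte genes averaged 0.55 (adjusted p = 0.147), with 1 of 8 members past the threshold, or 2 when adjusted over the list alone. It was Ifitm6, an interferon-induced membrane protein of myeloid cells, which rose by 2.58 ± 0.32 and was detected on 1 of 3 control arrays. T and NK cell genes averaged 0.34 (adjusted p = 0.102), with 1 of 13 past the threshold, also when adjusted over the list alone: Cd3d, a subunit of the T cell receptor complex, was up by 1.58 ± 0.28 and detected on 2 of 3 control arrays. B cell genes averaged −0.18 with a median of 0.02 (adjusted p = 0.519).

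Of the 15 measured cytokines and chemokines, 2 rose, or 4 when adjusted over the list alone, and the list did not pass (mean 0.43, adjusted p = 0.0988). Its mean was 0.27 without control 2, 0.14 within the brighter and 0.84 within the dimmer arrays. The risen genes were Il1b, a pro-inflammatory cytokine (2.27 ± 0.46), and Ccl4, a chemokine (2.10 ± 0.27). A second probe of Ccl4, dimmer than the first, gave 0.03. Without ventilated 1 the log2 fold change of Il1b was 2.05 (adjusted p = 0.0679), and 4 other omissions also ended its call. Among 15 genes of NF-kB feedback only Nfkbib, an inhibitor of NF-kB, passed over all genes (2.15 ± 0.27), while adjusted over the list alone 3 rose and 1 fell. The list shifted upward by a mean of 0.46 (adjusted p = 0.0187; adjusted p = 0.175 with an estimated correlation), a call lost without control 3 (mean 0.44), without ventilated 1 (mean 0.42) and with array brightness as a block (mean 0.46, adjusted p = 0.0538).

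The list of glucocorticoid-induced genes shifted upward. Of 18 measured members 8 rose and none fell, or 11 and none when adjusted over the list alone, with a mean log2 fold change of 1.25 (adjusted p = 1.2e-11; adjusted p = 0.0714 with an estimated correlation). The list score was 1.25 ± 0.12 (SD, n = 5), above all controls (SD 0.19, n = 3; exact permutation p = 0.0179), and the mean was 1.20 within the brighter and 1.40 within the dimmer arrays. The largest changes were those of Il1r2, which is also on the neutrophil list, and Cdkn1a. Among members that did not pass, chosen after their values were seen, Tsc22d3 stood at −0.58 ± 0.31, Dusp1 at −0.24 ± 0.28, Glul at −0.20 ± 0.27 and Per1 at 0.32 ± 0.34. Of the 18 members 7 also stand on other lists, Il1r2 and Lcn2 among them on the neutrophil list. Of 18 oxidative stress and metallothionein genes 3 rose, or 6 when adjusted over the list alone, with a list mean of 0.58 (adjusted p = 0.00701; adjusted p = 0.125 with an estimated correlation). The call was also lost when detection was required on all arrays, at a mean of 0.27. Within the dimmer arrays, which hold a single control, the mean was 0.62. Mt2 and Mt1, which bind zinc and copper, led them, and the other was the cystine transporter Slc7a11 (1.87 ± 0.25), chosen after its values were seen. Mt1 rose by 2.32 ± 0.23, from 11.46 ± 0.37 (SD, n = 3) to 13.78 ± 0.20 (SD, n = 5). Both are also members of the glucocorticoid-induced list.

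Genes downstream of interleukin-6 and STAT3 shifted upward, with 2 of 17 members past the threshold, 7 when adjusted over the list alone, and a list mean of 0.82 (adjusted p = 8.17e-07; adjusted p = 0.175 with an estimated correlation). They were Lrg1, a secreted glycoprotein of the acute phase (1.96 ± 0.26), and Socs3, a feedback inhibitor of cytokine signalling (1.77 ± 0.20). Of the 17 members 5 also stand on other lists, with Lcn2 on the neutrophil list, and ventilated 1 had the highest score of both lists, 1.20 here and 2.84 for neutrophils. Of 15 genes of the p53 and growth-arrest list 6 rose and none fell, the same numbers as when adjusted over the list alone, with a mean of 0.70 (adjusted p = 0.000125; adjusted p = 0.0714 with an estimated correlation). Cdkn1a and Gadd45g, a growth-arrest gene (1.73 ± 0.29), moved most. Within the brighter and dimmer arrays the means were 0.68 and 0.89 for the interleukin-6 list and 0.64 and 0.83 for the p53 list. Hypoxia-inducible genes shifted upward by a mean of 0.51 with none of 13 members past the threshold over all genes and 3 when adjusted over the list alone (adjusted p = 0.0128; adjusted p = 0.278 with an estimated correlation). This call was lost without control 2, at a mean of 0.29, and within the brighter arrays, at 0.36, against 0.89 within the dimmer arrays; it was also lost by fry and with array weights. Hk2, a hexokinase, had the smallest p of the list (1.18 ± 0.27, adjusted p = 0.0593).

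Of 19 matrix and protease genes 3 rose, or 5 when adjusted over the list alone, with a list mean of 0.54 (adjusted p = 0.00208; adjusted p = 0.225 with an estimated correlation). Eln, which encodes elastin, rose by 2.20 ± 0.38, and Lox, the enzyme that cross-links elastin and collagen, by 1.56 ± 0.31. The other member past the threshold, chosen after its values were seen, was the gelatinase Mmp9 (1.32 ± 0.26), also on the neutrophil list. Without control 3 the log2 fold change of Eln was 1.78 (adjusted p = 0.0717), the list mean was 0.43 and the list's adjusted p 0.0511. Of 17 cell junction genes 1 rose and 1 fell, or 2 and 1 when adjusted over the list alone, and the list did not pass (mean 0.24, camera adjusted p = 0.519). Its mean was 0.07 without control 2, 0.09 within the brighter and 0.57 within the dimmer arrays. Cldn4, an epithelial tight junction protein, rose by 2.66 ± 0.43, a call lost without control 3 at 2.53, and Gja5, the connexin of arterial endothelium, fell by 1.81 on the log2 scale (SE 0.21, adjusted p = 0.003). Plaur, the urokinase receptor, rose by 1.53 ± 0.32 and was the only 1 of 11 coagulation and fibrinolysis genes to pass, also adjusted over the list alone. Maff, a small basic leucine zipper factor, rose by 1.43 ± 0.20, against 0.38 by a second probe, and was the only 1 of 17 immediate early genes to pass, or 1 of 2 adjusted over the list alone. Nfil3, a basic leucine zipper repressor linked to the circadian clock, rose by 2.65 ± 0.30 and was the only 1 of 14 clock genes to pass over all genes. Adjusted over the list alone 2 clock genes rose, Nfil3 and Cry2 (1.38 ± 0.31), and 2 fell, Dbp (−1.90 ± 0.50) and Per2 (−0.87 ± 0.27); the last 3 were chosen after their values were seen. The means of these 3 lists were 0.18, 0.33 and 0.16 (adjusted p = 0.519, 0.0771 and 0.668). Without control 2 the coagulation mean was −0.01 and the clock mean −0.0047, and without control 3 the immediate early mean was 0.19.

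Hspa1a, which encodes the inducible heat shock protein of the HSP70 family, fell by 3.63 on the log2 scale (SE 0.62, adjusted p = 0.0185). Its control values were widely spread, at 8.26 ± 1.83 (SD, n = 3), and it was detected on 2 of the 5 ventilated arrays. Its log2 fold change was −4.67 without control 1, −2.96 without control 2 and −3.25 without control 3 (adjusted p = 0.0856), and leaving out ventilated 2, 3, 4 or 5 also ended the call, at −3.64 to −3.57. Fbxo30, a ubiquitin ligase subunit, had a log2 fold change of −2.75 ± 0.37, and the signalling ligand Wnt3a of −2.24 ± 0.32. Lbh, a transcription cofactor, stood at −2.08 ± 0.39 and Tcf21, a transcription factor of lung mesenchyme, at −2.04 ± 0.37. Gpr182, a receptor of endothelial cells, stood at −1.93 ± 0.33 and Synm, an intermediate filament protein, at −1.88 ± 0.28. Arhgef15 stood at −1.77 ± 0.32. Fmo1, a flavin-containing monooxygenase, fell by 1.74, from 11.86 ± 0.16 (SD, n = 3) to 10.12 ± 0.15 (SD, n = 5). The adjusted p of these falls lay between 0.003 and 0.0284. Fbxo30 was detected on 3 and Wnt3a on 4 of the 5 ventilated arrays. Dimmer second probes of Synm and Arhgef15 gave −0.55 and −0.67.

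Of 14 heat shock genes 2 fell and none rose, while adjusted over the list alone 3 fell and 1 rose, with a list mean of −0.60 (adjusted p = 0.0128; adjusted p = 0.175 with an estimated correlation). They were Hspa1a and Chordc1, a cochaperone of HSP90, which fell by 1.36 (SE 0.30, adjusted p = 0.0466). Without control 3 its log2 fold change was −1.02 (adjusted p = 0.145). The list score was −0.60 ± 0.07 (SD, n = 5), below all 3 controls (SD 0.30; exact permutation p = 0.0179). Without control 3 the list mean was −0.44 and its adjusted p 0.0511. The mean was −0.65 within the brighter and −0.53 within the dimmer arrays. The list did not pass with a common median or with detection required on all arrays. Interferon-stimulated genes shifted downward by a mean of −0.33 (camera adjusted p = 0.0164, or 0.437 with an estimated correlation). By list score 3 of the 5 ventilated mice lay below all controls (exact permutation p = 0.107). Gbp2, an interferon-induced GTPase, was the only 1 of 17 to fall over all genes, by 1.15 (SE 0.22), and 3 fell when adjusted over the list alone. The list call was lost without control 3, at a mean of −0.25, and with array brightness as a block, at −0.27 (camera adjusted p = 0.0586). It was also lost with a common median, by fry, and over arrays numbered 1 to 3 with or without the replicate block. Endothelial genes shifted downward by a mean of −0.30 (adjusted p = 0.0338; adjusted p = 0.437 with an estimated correlation), with 1 of 16 past the threshold, Sox18, a transcription factor of endothelium, which fell by 1.63 (SE 0.27). That list call was lost without control 1, control 2 or ventilated 3, at means of −0.24, −0.32 and −0.23. It was also lost with array brightness as a block, at −0.25 (camera adjusted p = 0.0929), and within the brighter arrays, at −0.16. A common median, the deposited values, detection on all arrays, array weights, fry and leaving out the dimmest array of each group ended it too. The endothelial list score gave an exact permutation p of 0.0536.

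**Figure D3:**
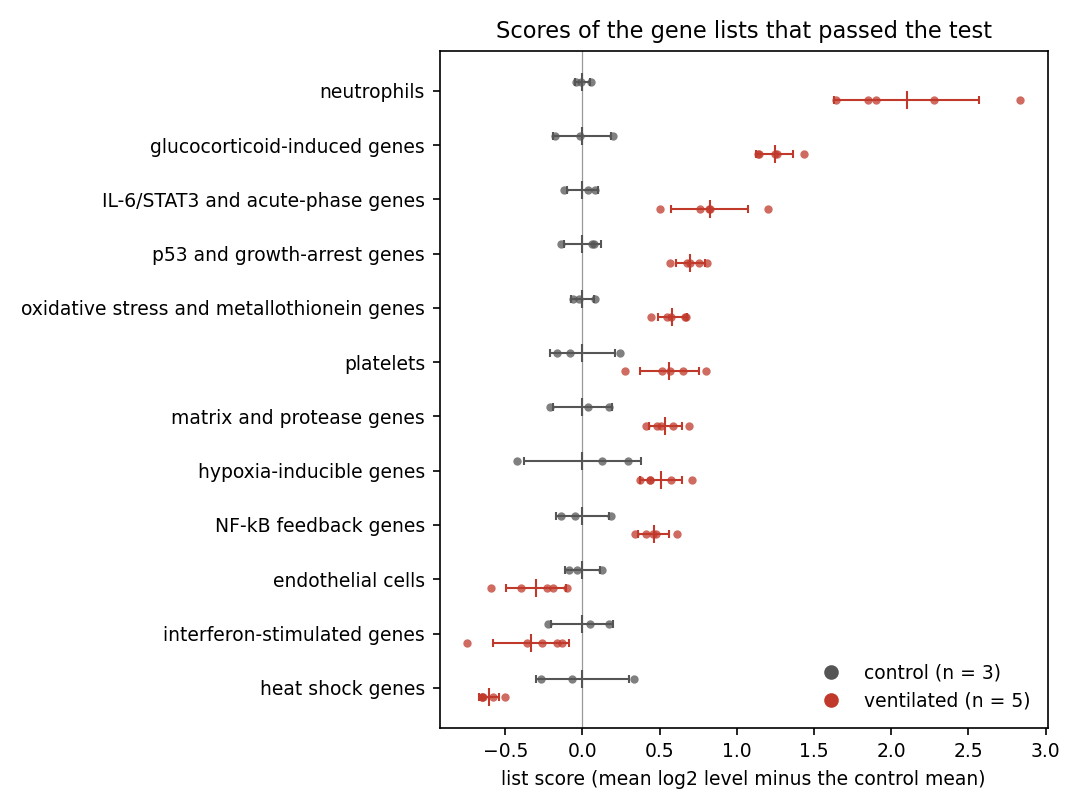
Each row shows, per mouse, the mean log2 level of a gene list minus its mean over the controls, with a point per mouse, a tick at the group mean and a bar of 1 SD either side, for 3 control mice in grey and 5 ventilated mice in red and for the 12 lists that passed the test. Neutrophil scores of the ventilated mice lie between 1.64 and 2.84, and the controls between −0.04 and 0.05.

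The 12 lists that passed were 9 shifted upward and 3 downward of 42 tested. With a correlation estimated per list none of them passed, and 9 of the 42 reached an unadjusted p under 0.05; by fry 9 lists passed. Score tests of the 42 lists gave an exact permutation p under 0.05 for 14, of which none passed after adjustment (smallest adjusted p 0.0625). Among the 56 splits of the 8 arrays into 3 and 5, 9 gave at least 12 lists, the real split included, so the number of lists alone does not set the ventilated lungs apart.

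The 30 other lists did not pass. List means were 0.22 for alveolar type 2 cells, −0.18 for alveolar type 1 cells, 0.02 for club cells, whose median was −0.17, and −0.38 for ciliated cells. Their members with the smallest p were the chemokine Cxcl15 (0.35 ± 0.22), Cyp2b10 (−0.73 ± 0.21), the club cell enzyme Cyp2f2 (−0.82 ± 0.29) and Sec14l3 (−0.79 ± 0.27). Ciliated genes came nearest to the threshold, with an adjusted p of 0.051. Means were 0.11 for fibroblasts, −0.20 for smooth muscle, −0.16 for alveolar macrophages, 0.29 for mesothelium, 0.31 for thymus and −0.23 for adipose tissue. Without control 2 the mean was −0.01 for mesothelium, 0.02 for fibroblasts, −0.36 for alveolar macrophages and −0.30 for club cells, and without control 1 it was 0.04 for adipose tissue, −0.08 for smooth muscle and 0.35 for club cells. Among fibroblast genes Tcf21 alone passed, downward. The smallest p on the other lists belonged to Lmod1 (−0.54 ± 0.25), Car4 (−0.57 ± 0.27), Krt8 (0.79 ± 0.25), Satb1 (1.12 ± 0.28) and Car3 (−1.11 ± 0.43), in that order. Cardiac muscle genes averaged −0.05, with a median of 0.12 and a mean of 1.31 within the dimmer arrays, and skeletal muscle genes −0.62, with Ankrd1 at −1.49 ± 0.49 and Tnnt3 at −1.11 ± 0.60. Without control 1 the mean was 0.58 for the cardiac and 0.51 for the skeletal list, both reversed in sign, while without control 2 they were −0.54 and −1.34. Within the brighter and dimmer arrays the skeletal mean was −1.53 and 0.96. Without control 1 Ankrd1 stood at −0.78, Tnnt3 at −0.10 and Car3 at −0.42. Hdc, the only mast cell and basophil gene measured and also a member of the neutrophil list, stood at 0.80 ± 0.26. Erythroid Hbb-bt stood at 1.22 ± 0.40, platelet Gp5 at 0.88 ± 0.30 and B cell Vpreb3 at −1.36 ± 0.38, none past the threshold. Without control 2 Hbb-bt stood at 0.70 and Gp5 at 0.53, and Hbb-bt at 0.34 within the brighter and 2.51 within the dimmer arrays. The measured Y-linked genes Kdm5d and Uty stood at −0.11 ± 0.35 and −0.30 ± 0.23, detected on 5 and 3 of the 8 arrays.

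Among pathways that did not pass, targets of stretch-responsive YAP and SRF averaged −0.19, with Ankrd1 the member of smallest p, but 0.00 without control 1 and −0.36 without control 2, and ligands of the EGF receptor 0.00, with Epgn at 0.46 ± 0.26. Endoplasmic reticulum stress genes averaged 0.02 (Herpud1, 0.55 ± 0.23), cell cycle genes 0.20 (Plk1, 0.86 ± 0.30) and endothelial activation genes 0.17 (Nos3, 0.80 ± 0.23). Other kept probes of Nos3 gave 0.28 and 0.12. Cholesterol and fatty acid synthesis genes averaged −0.18 (Srebf1, −1.21 ± 0.29), ion and water transport genes 0.14 (Aqp4, −1.21 ± 0.30), and TGF-beta and BMP response genes −0.09 (Bmp4, −0.81 ± 0.24). The ion transport mean was 0.02 without control 3 and 0.26 without control 2. The TGF-beta mean was −0.24 without control 2 and at most 0.07 with 1 array left out. MHC class II and antigen presentation genes averaged −0.26 (Ciita, −0.89 ± 0.38). The adjusted p of these single genes lay above the threshold. Some lists that did not pass with all arrays passed when 1 was left out: cytokines and immediate early genes without control 1 (means 0.54 and 0.49), skeletal muscle without control 2, MHC class II without control 3 (−0.39), T and NK cells without ventilated 2 (0.41), ciliated cells without control 1 or ventilated 4 (−0.43 in both) and cholesterol synthesis without ventilated 5 (−0.26). Immediate early genes also passed without ventilated 3 and erythroid genes without ventilated 5.

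Of all 204 changed features, 52 stayed past the threshold in each of the 8 fits that left out 1 array, and 51 in none. Of the 38 named genes past the threshold, which include the largest changes, 21 stayed past it in each. Retnlg, S100a9, S100a8, Il1r2, Cdkn1a, Mt1, Mt2, Socs3 and Lrg1 were among these. The other 17 lost the call in 1 to 7 of the fits. They were Fpr2, Camp, Hspa1a, Lbh, Tcf21, Gpr182, Arhgef15, Il1b, Chordc1, Plaur, Eln, Lox, Gbp2, Gadd45g, Cldn4, Sox18 and Cd3d. Their sign could not turn in these fits, because their groups did not overlap. Their highest adjusted p in these fits was 0.145. With scaling to a common median instead of quantile normalization, no gene passed in the limma fit and 116 had an unadjusted p under 0.05. In the deposited values 7 genes passed, each of them also among the 204, and 695 had an unadjusted p under 0.05.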

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

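No test in this part was chosen after the results were seen. In each group of 5 ventilated arrays, the highest and lowest values were compared with the others by Dixon's gap test, for 64 genes, 44 list scores and 4 measures of the arrays. Of these 112 groups 4 held a sample far from the others, while chance picks out about 1 in 20 groups, so the number is no larger than chance gives. The 3 control arrays are too few for this test.

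The antimicrobial gene Camp stood highest in ventilated 1, at a normalized log2 level of 8.78, with the nearest ventilated mouse at 6.89. The metallothionein gene Mt1 stood lowest in ventilated 2, at 13.43, with the nearest at 13.85. The score of MHC class II and antigen presentation genes was highest in ventilated 1, at −0.0326, with the nearest at −0.287. The adipose score was highest in ventilated 4, at 0.12, with the nearest at −0.27. None of the 4 array measures was so far apart, and no explanation was tested for these 4 values.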

How the results depend on the processing

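The alternatives for array brightness were chosen after the arrays were seen, and all others were planned. The 204 changed genes kept their direction in each alternative that measured them (98 of 98 under the strict detection filter), while how many passed varied. Their ventilated and control values did not overlap. Leaving arrays out, or changing the threshold or set test, therefore could not turn a direction.

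Counts of changed genes were 314 with cyclic loess, 838 with arrayWeights, 412 at an adjusted p under 0.1 and 53 under 0.01. In the limma fit 0 genes passed after scaling to a common median (116 at an unadjusted p under 0.05), and 7 in the deposited value table (695 unadjusted). Counts were 569 with brightness as a covariate, 315 with the brighter and dimmer arrays as a block, 11 in the bright arrays only, 86 in the dim arrays only and 120 without the dimmest array of each group. The last 3 rest on fewer arrays; for the others the cause was not tested. Leaving out 1 array gave 68 (without control 3) to 164 (without control 2). Not every feature in these counts was among the 204. Of the 120, 96 were, and of the 164, 125 were.

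Counts changed at least 2-fold were 95 with normexp and an offset of 50, 89 without background correction, 0 with a common median, 7 in the deposited table, 368 with arrayWeights, 24 with treat against a fold of 1.5, and 401 with brightness as a covariate. They were 11, 86 and 120 in the bright arrays only, the dim arrays only and without the dimmest arrays. Leaving out 1 array gave 68 to 163. Offsets and no background correction shrink folds near the background; for the others the cause was not tested.

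The share of changed genes that rose was 63.2%, against 47.7% under the strict filter, 50.6% with arrayWeights, 81.1% at an adjusted p under 0.01, 91.9% in the dim arrays only, and 100% in the bright arrays only and in the deposited table. It was 60.4% to 79.4% with 1 array left out. The median log2 fold change of all genes was 0.014, and −0.112 with a common median, to which changes under that scaling are relative. It was 0.115 in the dim arrays only.

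Of 12 lists, 0 passed in camera with an estimated correlation (9 unadjusted; 9 passed by fry) and 5 in the dim arrays only. Leaving out 1 array gave 9 to 14 lists of the 42 tested, and 10 to 15 list scores. The cardiac muscle list mean reversed and passed in the dim arrays only, at 1.31, with 1 control there; without control 1 it was 0.58 without passing. Of 1126 list means under alternatives 954 kept their sign and side of the threshold, 49 newly passed and 58 no longer passed. Another 64, of 17 lists, turned sign while past the threshold in neither fit, the skeletal muscle mean among them (0.51 without control 1, 0.96 in the dim arrays only). List scores within the bright or dim arrays have too few splits to pass.

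Same-numbered arrays deviated from their group means with correlations of −0.34, −0.36 and 0.36, and differently numbered ones with −0.55 to 0.53. No pairing by replicate number showed, but these few values cannot exclude one. With the replicate number as a block, over arrays 1 to 3, 2 genes passed and 2 changed at least 2-fold (843 unadjusted), against 30 and 30 in the same 6 arrays without the block. The slide as a block was not run because the files give no slides. Low signal over background limits genes detected on few arrays: 6 changed genes were detected on no control array.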

Other observations

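The genes in this part and the tests of the neutrophil, glucocorticoid and heat shock patterns were chosen after their results were seen; the test of control 2 and the counts of splits were planned. Among glucocorticoid-induced genes, Fkbp5, a cochaperone of the glucocorticoid receptor, rose by 2.33 ± 0.24 on the log2 scale (SE; limma adjusted p = 0.00155). The metabolic genes Angptl4 and Pdk4 rose by 1.87 ± 0.25 and 1.81 ± 0.25. Sphk1, which makes sphingosine 1-phosphate, rose by 2.57 ± 0.23, and Ramp3, a subunit of adrenomedullin receptors, by 2.63 ± 0.27. Egfr, the receptor of EGF, rose by 1.79 ± 0.26, while the list of its ligands did not pass. On myeloid cells, Cd14, a co-receptor for endotoxin, rose by 1.68 ± 0.23 and Cd177, a neutrophil surface protein, by 2.11 ± 0.39. The neutrophil gene Clec4d rose by 2.14 ± 0.37. Cstdc4, a cystatin, was detected on no control array and was at least 4.41-fold higher.

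Among the falls, the morphogen Shh fell by 1.45 (SE 0.29, limma adjusted p = 0.0358) and the Notch target Nrarp fell by 1.43 (SE 0.30). The matricellular gene Ccn5 fell by 1.52 (SE 0.30). The chaperone genes Hspa2 and Dnaja4, which were on no list, stood at −1.02 ± 0.21 and −1.14 ± 0.24, both past the threshold. In the p53 and growth-arrest list Gadd45a (1.36 ± 0.26), Trp53inp1 (1.16 ± 0.21), Sesn1 (1.01 ± 0.21) and Fas (1.09 ± 0.24) rose beside Cdkn1a and Gadd45g.

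Of the 56 splits of the 8 arrays into 3 and 5, 1, the real one, gave as many as 204 changed genes, and the highest other gave 31. For changes of at least 2-fold it was likewise 1 split, with 196 against 31. A share of 1 in 56 is the smallest these splits can give, and only the main normalization was used. These counts set the real split apart without excluding chance. The split with 31 grouped control 2 with ventilated 1 and 4, all among the dimmer arrays. It gave 2278 features at an unadjusted limma p under 0.05, against 1656 for the real split. At least 12 lists were given by 9 of the 56 splits and 16 by the highest other, so chance cannot be excluded for the number of lists.

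More blood in the ventilated lungs might explain the rise of neutrophil genes. The neutrophil score exceeded the mean of the erythroid and platelet scores by 1.56 ± 0.44 (SD, n = 5, exact permutation p = 0.0179, the smallest that 56 splits can give). That argues against an equal log2 rise of all blood cell genes. It does not exclude blood as a source. Genes with unlike control levels, such as Camp and Il1r2, which were undetected on the controls, need not show an equal log2 rise. The erythroid mean was 0.28 to 0.74 with 1 array left out, below the neutrophil mean in each case. Without the dim control 2 array the neutrophil list mean was 2.10, as with all arrays, which argues against that array as the source. The camera adjusted p there, 1.64e-19 at the preset correlation, rests on the spread between genes. With all arrays and an estimated correlation the camera adjusted p was 0.0952. Entry of neutrophils with ventilation, more neutrophils in the blood and induction in resident cells stay open, as untested.

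Glucocorticoid-induced genes were higher and heat shock genes lower in ventilated lungs, which might follow from another time of day at sampling. The mean of clock genes of the phase of Nfil3 minus that of the phase of Dbp differed between the groups by 1.42 (exact permutation p = 0.0179). Its SD was 0.50 in the ventilated mice (n = 5) and 0.33 in the controls (n = 3). Without Nfil3 the groups differed by 0.62 (exact permutation p = 0.143), with SDs of 0.39 and 0.56. Glucocorticoids shift clock genes too, so time of day cannot be told apart here. Cooling could raise Cirbp and Rbm3: Cirbp rose by 1.90 ± 0.23, while Rbm3 stood at 0.66 ± 0.26 (limma adjusted p = 0.249), which leaves cooling open. Without control 3 the heat shock mean was −0.44 (camera adjusted p = 0.0511), so a high level in that control may add to the fall. Ventilation itself, anaesthesia and stress stay open, as untested.

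Control 2 stood apart from the other arrays, which could follow from its dim signal. Over the tenth of genes brightest on the other arrays its median correlation was 0.714, against 0.802 for the next lowest array, control 1, with an SD of 0.0247 among the other arrays. The lower likeness of control 2 thus held among genes bright on the other arrays. These genes may still be dim on control 2 itself, so its dim signal stays open as a cause. The quality of its RNA and a difference of the mouse itself stay open, and no biological explanation was tested.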
